A study of Mus musculus with 24 samples.

How the data were processed

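Bulk RNA was measured in 24 libraries from a mouse glioblastoma stem cell line, in 6 groups of 4. Per the labels, the line, called NPE, carries deletions of the tumour suppressors Nf1 and Pten and expresses EGFRvIII, a truncated and constitutively active epidermal growth factor receptor. Its knockout derivative (KO) lacks Ilk, the gene of integrin-linked kinase, and a further line (Rx) re-expresses ILK. The sources used here do not say from which line Rx was derived. The genotype label of Rx is the same as that of NPE, so its identity here comes from the sample titles and the series' design text. Each line was sampled untreated and after 24 h with BMP-4, which the design text describes as a factor that drives astrocyte differentiation. The dose is 10 ng per mL in the sample labels, while the protocol text gives the same number per microlitre, so the dose is uncertain.

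Per the labels' protocols, RNA was extracted with a Qiagen kit, and 110 ng went into a 3' mRNA library kit (QuantSeq), which yields about 1 tag per transcript near its 3' end. Values therefore need no correction for transcript length, and a tag can lie outside a deleted part of a gene. Per the submitters' processing notes, the genome build was mm9 and DESeq2 was used. The aligner, the counting program, the strand setting and all versions are not given in the sources used here. The deposited files hold whole-number counts per Ensembl gene ID, not normalized, with closing lines for reads in no gene, in overlapping genes and with several alignments, in the form that htseq-count writes. Those closing lines stayed out of library sizes and tests. Reads in no gene came to a mean of 5.92% of the gene reads (4.83% to 6.75%), ambiguous reads to between 0.621% and 0.734%, and reads without a unique alignment to between 80.4% and 116%. No value column was left unmatched to a sample.

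Symbols came from a table of gene names, which matched 47224 of the 47643 IDs (99.1%). The reference annotation used here (GENCODE M21, on GRCm38) is of another build than mm9, so no coordinates are given, and it served only for chromosomes and neighbouring genes. It gave a chromosome to 13681 of the 13710 tested genes (99.8%), and 20 chromosomes held at least 50 of them. Without a stated strand, reads of genes that overlap on opposite strands cannot be told apart. This concerns Ilk, which meets Taf10 tail to tail, and Xist, which overlaps Tsix.

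Gene reads per library ranged from 10050219 to 19808731, with a median of 13953162.5. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15). This left 13710 genes, which held 99.96% of the reads. Counts were scaled by the trimmed mean of M values, and a negative binomial quasi-likelihood model with 1 mean per group was fitted to all 24 libraries in edgeR 4.0.16 under R 4.3.3, with 18 residual degrees of freedom. The common biological coefficient of variation was 0.318. A gene was called at a Benjamini-Hochberg-adjusted p under 0.05 from edgeR's quasi-likelihood F test, over all tested genes of a comparison. Levels are CPM, the counts scaled to library size, log2 CPM has a prior count of 2, and errors of levels are SD over 4 libraries. The 12 comparisons were the 3 pairs of lines in each of the 2 treatments, BMP-4 against untreated in each of the 3 lines, and the 3 differences between the lines' responses (interaction terms).

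Replicate pairs were compared before averaging: the 36 pairs had a chi-square of 8.37 to 34.5 per degree of freedom, so no pair agreed within sampling noise. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical. Reads carry no molecular identifiers that the labels mention, so counting intervals (95%, exact Poisson) and floors cover counting error only. A group with 0 counts in a gene was set to a floor of 3 counts over the group.

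The following choices were made before the data were examined. Text names Ilk, Nf1, Pten, Egfr and Stat3 always. It names the largest changes per direction among called genes with a mean log2 CPM of at least 4 and a symbol other than a clone name. In comparisons of groups the libraries also had to lie apart without overlap, so each such gene moved the same way in 4 of 4 libraries. The number per direction was 10 for KO against NPE untreated, BMP-4 in NPE and the difference of these responses, and 5 elsewhere. Up to 4 members of each gene list with the smallest p were named too. The 23 lists held 465 genes, of which 463 were in the files and 384 were tested: ILK complex and focal adhesion, extracellular matrix, actin and SRF targets, YAP and TEAD targets, astrocyte, neural stem and progenitor, oligodendrocyte lineage, neuron, mesenchymal glioblastoma, STAT3 pathway, BMP and SMAD targets, BMP receptors and signal, cell cycle, cell cycle inhibitors, receptor tyrosine kinase feedback, interferon and antigen presentation, hypoxia and glycolysis, endoplasmic reticulum and amino acid stress, heat shock and RNA handling, microglia and leukocyte, endothelial, fibroblast and mural, and ependymal.

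Lists were tested on log2 CPM with camera in limma 3.58.1, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each test was repeated with a correlation estimated from the data and with fry, which asks whether a list's genes move on balance one way. Of 276 list tests, 89 were called, 61 of them also with an estimated correlation, and fry called 170. Median, mean and test direction differed in sign in 72 of the 276 tests and in 0 of the called ones. Where a called list has no such p beside it in the text, it was called with an estimated correlation too. Counts adjusted over the list alone are given beside those over all genes. Shares of reads and shifts of chromosomes were compared between groups with two-sided exact permutation tests, in which 0.0286 is the smallest p that 4 against 4 can give.

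The gene test of 2 comparisons and the list test of 1 were tried on simulated counts, and the other tests were not. Counts were drawn from the means of untreated NPE in every group, with the real library sizes. Few genes were changed, whereas 4106 (KO against NPE untreated) and 3602 (difference of responses between KO and NPE) were called in the data. For KO against NPE untreated (12500 genes), 36.4% of genes changed 1.5-fold, 60% of those changed 2-fold and 87.7% of those changed 4-fold were recovered, and 9 unchanged genes made up 6.98% of the calls, above the 5% aimed at. For the difference of responses between KO and NPE (12482 genes) the recovered shares were 7.81%, 39.1% and 77.3%, and 1 unchanged gene made up 1.22% of the calls. In a simulated BMP-4 response of KO (12498 genes), an astrocyte list shifted 1.5-fold was called and 0 of 20 unshifted lists were. Genes were drawn independently of each other, so this does not show how often lists of correlated genes are called wrongly.

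Alternatives were size factors by relative log expression (RLE), no filter, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, thinning to 10050219 reads, a required fold change of 2, and leaving out each library in turn. Leaving out mitochondrially encoded genes, and leaving out genes of chromosomes 7, 10 and 19, were added after the data had been seen.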

Results

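Gene expression was profiled in a mouse neural stem cell model of glioblastoma to ask how integrin-linked kinase (ILK), an adaptor that couples integrins to the actin cytoskeleton, affects the cells' state and their response to a differentiation signal. The parental NPE line, its ILK knockout (KO) and an ILK re-expressing line (Rx) were each sampled untreated and after 24 h with BMP-4, with 4 libraries in each of the 6 groups. BMP-4 is a bone morphogenetic protein that drives neural stem cells towards astrocytes. Tags were counted at the 3' ends of transcripts, and the 24 libraries held between 10050219 and 19808731 gene reads. At this depth, 13710 genes were tested.

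Ilk itself (ENSMUSG00000030890) was the first gene examined, since it checks the labels. It stood at 185 ± 22.7 CPM in untreated NPE, 27.4 ± 4.94 in untreated KO and 240.5 ± 50.4 in untreated Rx. With BMP-4 it stood at 196 ± 24.6, 16.7 ± 1.81 and 161 ± 16.1 CPM in the same order (SD, n = 4 each). The KO libraries thus kept 14.8% of the NPE level untreated and 8.51% with BMP-4. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the difference between KO and NPE was −2.75 ± 0.14 (SE) on the log2 scale untreated (adjusted p = 6.38e-19). Rx exceeded KO by 3.13 untreated and 3.27 with BMP-4. Between Rx and NPE, Ilk differed by 0.38 untreated (adjusted p = 0.0419) and by −0.28 with BMP-4 (adjusted p = 0.142). The former call ended without NPE replicate 1, 2 or 3 or Rx replicate 2, 3 or 4 (adjusted p = 0.176, 0.127, 0.0555, 0.166, 0.175 and 0.0863), and also with RLE size factors, the replicate block or DESeq2 (adjusted p = 0.051, 0.0601 and 0.0534). The deleted part of Ilk is not given in the sources used here, and a 3' tag outside it would check nothing. Reads of Taf10, which overlaps the end of Ilk on the opposite strand, could be counted with it, and Taf10 stood at 346 ± 20 CPM in untreated NPE and 551 ± 40.7 in untreated KO.

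Stat3, the transcription factor named in the series' title, was lower in KO and also in Rx than in NPE, and higher with BMP-4 in all 3 lines. Stat3 (ENSMUSG00000004040) stood at 266 ± 27.2, 111 ± 18.6 and 136 ± 8.92 CPM in untreated NPE, KO and Rx, and at 625 ± 41, 165 ± 20.6 and 261 ± 21.2 CPM with BMP-4 (SD, n = 4 each). Relative to NPE it fell by 1.26 in KO and by 0.97 in Rx untreated, and by 1.92 and 1.26 with BMP-4, on the log2 scale. Rx exceeded KO by 0.66 with BMP-4 and by only 0.29 untreated (edgeR quasi-likelihood, Benjamini-Hochberg-adjusted p = 0.0234). The latter call was lost without KO replicate 1 or 4 or Rx replicate 1 (adjusted p = 0.0847, 0.11 and 0.066). BMP-4 raised Stat3 by 1.24 in NPE, 0.57 in KO and 0.94 in Rx.

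Among the genes of the line's engineered lesions, Egfr (ENSMUSG00000020122) rose with BMP-4 from 105 ± 19.6 to 193 ± 8.7 CPM in NPE and from 56.8 ± 4.04 to 75.3 ± 8.79 in Rx (SD, n = 4 each). KO had 93.1 ± 6.61 and 108 ± 23 CPM, a difference that was not called. Reads of the transgene and of the mouse gene cannot be told apart here. Pten (ENSMUSG00000013663) gave 53.1 ± 2.23 CPM in untreated NPE, 26.4 ± 5.19 in KO and 43.5 ± 5.8 in Rx, and 19.7 ± 6.61, 14.9 ± 2.22 and 29.7 ± 4.21 CPM with BMP-4. Its difference between KO and NPE was −1.01 untreated, and −0.40 with BMP-4, where it was not called (edgeR quasi-likelihood, Benjamini-Hochberg-adjusted p = 0.112, and 0.0104 without NPE replicate 1). BMP-4 lowered Pten by −1.43 in NPE, −0.82 in KO and −0.55 in Rx. The change in Rx (adjusted p = 0.0218) was lost without untreated Rx replicate 1, 3 or 4 or BMP-treated Rx replicate 2, 3 or 4 (adjusted p up to 0.103). Pten was higher in BMP-treated Rx than NPE by 0.59 (adjusted p = 0.0294), which was lost without NPE replicate 1 or 3 or Rx replicate 1 or 3 (adjusted p up to 0.178). Nf1 (ENSMUSG00000020716) lay between 5.74 ± 2 and 6.78 ± 1.48 CPM in the 6 groups and was called in none of the 12 comparisons (adjusted p of 0.834 or more by edgeR's quasi-likelihood test). For Nf1 and Pten too, tags outside the deleted part check nothing.

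**Figure D1:**
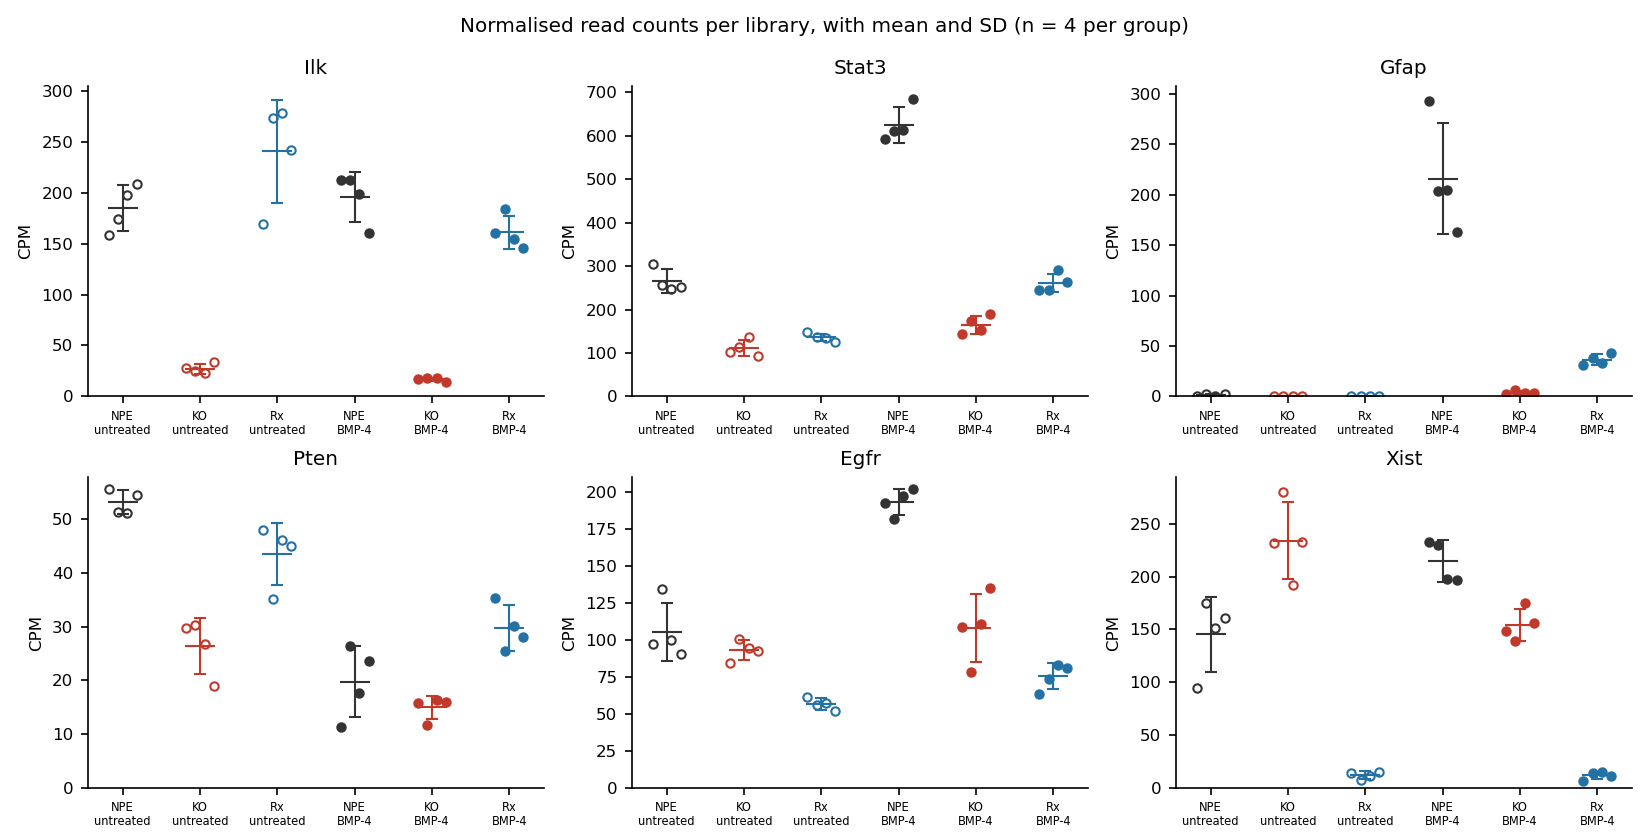
CPM of Ilk, Stat3, Gfap, Pten, Egfr and Xist in each of the 24 libraries (points), with the group mean and SD (n = 4). Ilk lay at 27.4 CPM or lower on average in both KO groups, and Gfap reached 216 CPM in BMP-treated NPE against 3.77 CPM in BMP-treated KO.

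In a principal component analysis of log2 CPM, the first component held 26.8% of the variance, the second 17.1% and the third 8.9%. BMP-4 moved NPE and Rx far along the first component, from scores of −52.7 to −30.3 up to 89.6 to 92.6 in NPE and from −41.0 to −34.4 up to 60.6 to 65.0 in Rx, but KO only from −70.7 to −58.9 up to −19.8 to −3.39. The second component set the KO libraries, all at −46.9 or lower, apart from all others, which lay at −2.03 or higher. The third held NPE at 28.0 or higher and Rx at −37.6 or lower.

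**Figure D2:**
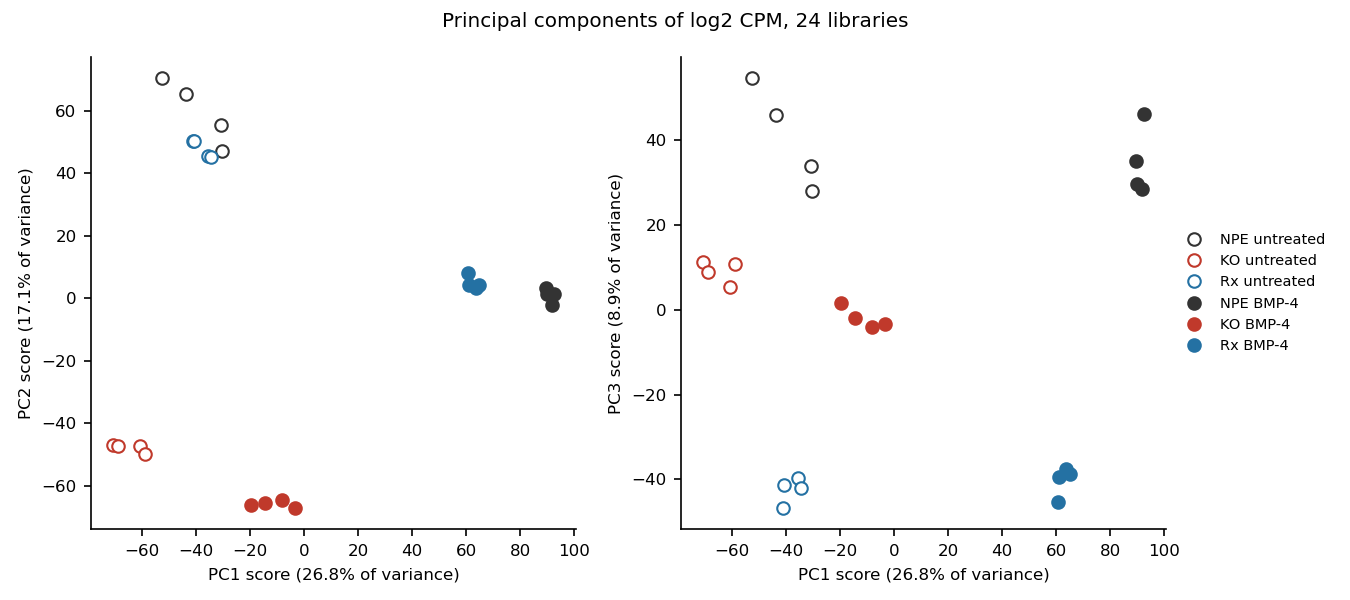
Principal component scores of the 24 libraries from log2 CPM of the 13710 tested genes, the first against the second component (left) and against the third (right), coloured by group. The components hold 26.8%, 17.1% and 8.9% of the variance.

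The comparison of untreated KO with untreated NPE asks how the line that lacks Ilk differs from its parent when kept as stem cells. Among the largest changes were those of Rbp1 and Adh7, which act on retinol. Rbp1, the cellular retinol-binding protein, fell from 691 ± 39.4 to 2.37 ± 0.815 CPM (log2 fold change −8.20 ± 0.20 SE). Adh7, an alcohol dehydrogenase that oxidises retinol, rose from 11.1 ± 1.68 to 519 ± 32 CPM (5.56 ± 0.30). Some secreted and glial proteins rose: Sparcl1, a matrix glycoprotein of astrocytes, from 35.2 ± 6.06 to 1146 ± 59.5 CPM (5.03 ± 0.16). So did the alarmin Il33 by 5.11 ± 0.39, the iron carrier Trf (transferrin) by 4.31 ± 0.35, and the calcium-binding S100b by 3.47 ± 0.29. The adhesion and cytoskeleton genes Ctnnal1 (3.27), Nrcam (3.07) and Nefl (2.64), Pidd1, which acts downstream of p53 (2.82), and the quinone reductase Nqo1 (2.58) rose too. Nnat, an imprinted proteolipid gene, fell by 7.72 ± 0.36, and the LIM-domain genes Trip6, a focal adhesion protein, and Lmcd1 fell by 4.91 and 3.91. The receptors Gper1 (−4.18) and Adora1 (−3.48), the cadherin Cdh22 (−3.50), the ubiquitin ligase gene Neurl1a (−4.13), Sez6 (−4.06) and the vesicle protein gene Syt7 (−3.32) were also lower. In all, 4106 of 13710 genes were called, 2062 higher and 2044 lower in KO (769 each with a 2-fold difference required). The 20 genes named here had a Benjamini-Hochberg-adjusted p of 1.11e-06 or less (edgeR quasi-likelihood). S100b lies on chromosome 10. Il33, Neurl1a, Syt7 and Pten lie on chromosome 19, whose genes as a whole were lower in KO, and Pidd1 and Ilk on chromosome 7, whose genes were higher.

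By lists fixed in advance, amino acid and endoplasmic reticulum stress genes had the smallest p in untreated KO. Of 19 measured, 13 fell and 3 rose (13 and 3 also adjusted over the list alone), with a median log2 fold change of −1.62 (camera, Benjamini-Hochberg-adjusted p = 2.24e-06; adjusted p = 0.0115 with an estimated correlation). Examples are Psat1, an enzyme of serine synthesis, which fell from 1542 ± 80.1 to 490.3 ± 43.5 CPM, the stress transcription factors Atf4 (−1.62) and Atf5 (−1.80), and Trib3 (−4.10), a pseudokinase induced by them. Matrix genes were mostly lower, 13 of 23 falling and 3 rising (14 and 3 adjusted over the list alone, median −0.81). They were led by the neural proteoglycans Ncan (−2.72) and Bcan (−1.70) and the basement membrane collagens Col4a1 (−1.57) and Col18a1 (−1.39). Of 25 astrocyte markers 12 fell and 3 rose (12 and 3 adjusted over the list alone, median −0.82). Mlc1 (−1.98), Acsbg1 (−1.69) and Atp1b2 (−1.98) fell, while Sparcl1 and S100b rose. Neural stem and progenitor genes fell in 10 of 23 cases and rose in 1 (11 and 1 adjusted over the list alone, median −0.38). Among them were the forebrain transcription factors Lhx2 (−1.55), Foxg1 (−1.09) and Sox1 (−7.80, from 22.2 ± 4.01 to 0.0879 ± 0.135 CPM). Hypoxia and glycolysis genes such as Ndrg1 (−2.52) and the angiogenic factor Vegfa (−1.56) fell in 11 of 19 cases and rose in 1 (11 and 1 adjusted over the list alone, median −0.66). These 4 lists were called by camera (Benjamini-Hochberg-adjusted p = 0.000974, 0.00152, 0.00218 and 0.000906 in this order), but not with an estimated correlation (adjusted p = 0.0678, 0.0614, 0.0614 and 0.0614).

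Cell cycle genes were slightly higher in untreated KO, 13 of 32 rising and 3 falling (13 and 4 adjusted over the list alone, median 0.16; camera adjusted p = 0.018, adjusted p = 0.287 with an estimated correlation and 0.0596 in a fit of the 8 libraries compared). The helicase gene Mcm7 (0.94), the mitotic genes Cdc20 (0.98) and Plk1 (0.71) and the proliferation marker Mki67 (0.97) were among the risers. ILK's own complex and focal adhesions did not shift as a set: 8 of 27 measured genes rose and 8 fell (10 and 8 adjusted over the list alone, median 0.05, camera adjusted p = 0.955). Nor was the STAT3 pathway list called (3 of 22 rose and 7 fell, median −0.29, camera adjusted p = 0.329), nor YAP and TEAD targets (4 of 14 rose and 3 fell, median −0.11, camera adjusted p = 0.643). Cspg4, a proteoglycan of oligodendrocyte precursors, had 1 count in the 4 untreated KO libraries against 9.66 CPM in NPE, a ratio of 528 with a 95% counting interval of 94.7 to 20800.

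The other lists were not called in untreated KO either, although single members moved. Oligodendrocyte lineage genes rose in 4 of 12 cases and fell in 5 (median 0.36, camera adjusted p = 0.639), and neuron genes rose in 4 of 11 and fell in 4 (median −1.39, camera adjusted p = 0.921), where Map2 (−2.35) and Stmn3 (−7.54) fell. Mesenchymal glioblastoma genes rose in 7 of 26 and fell in 9 (median −0.25, camera adjusted p = 0.643), actin and SRF targets in 1 and 6 of 15 (median −0.11, camera adjusted p = 0.121) and BMP and SMAD targets in 1 and 5 of 20 (median −0.36, camera adjusted p = 0.39). BMP receptors had a median of −0.10, interferon genes one of −0.26 and ependymal genes one of 0.09 (camera adjusted p = 0.603 each). Cell cycle inhibitors stood at 0.05 (camera adjusted p = 0.819), receptor tyrosine kinase feedback genes at 0.01 (0.643) and heat shock genes at 0.33 (0.518).

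**Figure D3:**
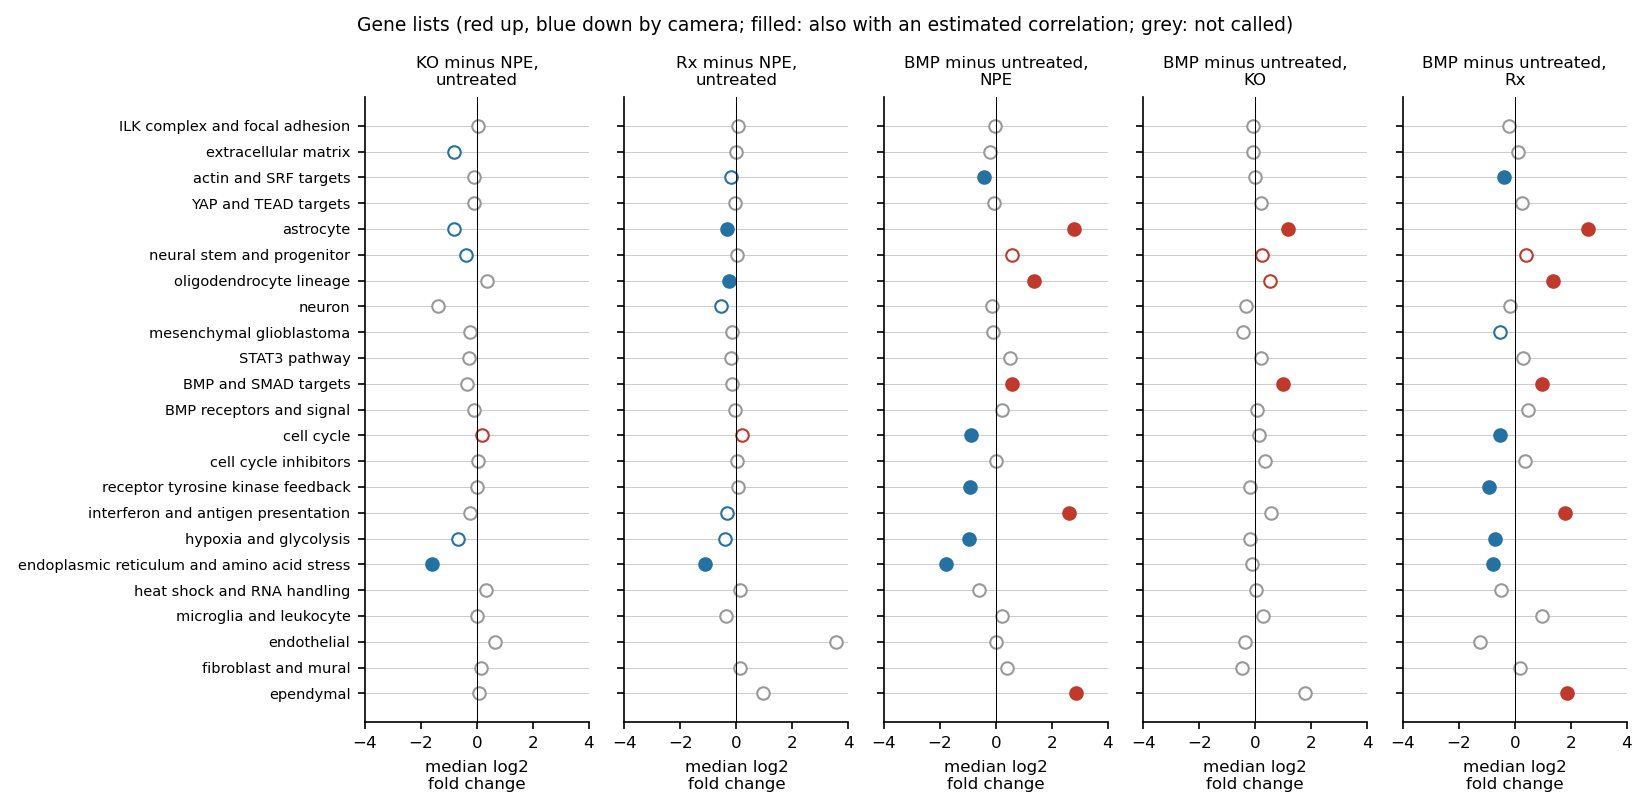
Median log2 fold change of the measured members of each gene list in 5 comparisons. Red and blue mark lists called higher or lower by camera, filled where also called with an estimated correlation, and grey marks lists not called; the cell cycle list has a median of −0.90 with BMP-4 in NPE and 0.14 in KO.

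The Rx line asks how cells labelled as re-expressing ILK differ from KO. The sources used here do not say whether Rx was derived from KO, so a value nearer to NPE need not be a return to it. Rbp1 stood in untreated Rx at 781 ± 87.9 CPM (8.38 ± 0.20 over KO), and Nnat (5.42), Trip6 (5.22), Lmcd1 (4.16) and Akap12, a kinase-anchoring scaffold (3.72), were higher than in KO too. Trf (−6.46), Sparcl1 (−6.42), Adh7 (−5.19), the myelination-associated Bcas1 (−6.70) and the chemokine Cxcl5 (−5.19) were lower (edgeR quasi-likelihood, Benjamini-Hochberg-adjusted p of 7.37e-10 or less for these 10 genes). In total 3451 genes differed between Rx and KO, 1764 higher and 1687 lower in Rx (596 and 635 with a 2-fold difference required). Stem and progenitor genes were higher in 13 of 23 cases and lower in 3 (14 and 3 adjusted over the list alone, median 0.50), including Foxg1 (1.55), Lhx2 (1.12) and Nes, the intermediate filament of neural stem cells (0.81). Matrix genes were higher in 10 of 23 cases and lower in 3 (12 and 4 adjusted over the list alone, median 0.34), with Bcan at 1.55 and Col18a1 at 1.66. Both calls (camera adjusted p = 0.00245 and 0.00653) were absent with an estimated correlation (adjusted p = 0.125 and 0.299). That of the matrix list was also absent in a fit of the 8 libraries compared (adjusted p = 0.0962).

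Of the 4106 genes called between KO and NPE, 2245 (54.7%) were called between Rx and KO in the opposite direction, 1193 lower and then higher and 1052 higher and then lower, and 51 in the same direction. Without the genes of chromosomes 7, 10 and 19, left out after the data had been seen, 1647 genes were reversed. On chromosome 19 alone, 198 genes were lower in untreated KO than NPE and 211 higher in untreated Rx than KO. Independent lists of these sizes would share 263 and 253.7 genes in the 2 opposite directions. Both comparisons use the same KO libraries. When these were split into separate pairs, the 6 splits gave between 1403 and 1447 reversed genes, and the fold changes correlated across genes with r between −0.344 and −0.292. Genes are not independent replicates. With the shared libraries r was −0.632, against −0.498 in simulations with no effect, and the covariance was −1.61 against −0.117. Of the reversed genes, 1787 were not called between Rx and NPE.

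Rx and NPE were not alike untreated: 1868 genes differed, 930 higher and 938 lower in Rx (256 and 358 with a 2-fold difference required). The adhesion gene Lrrn3 (2.23), the matrix gene Sned1 (1.99), Il17rd, an inhibitor of fibroblast growth factor signalling (1.89), the aldo-keto reductase Akr1c13 (1.82) and the polarity gene Prickle1 (1.80) were higher. Bcas1 (−4.36), Sez6 (−4.30), Syt7 (−3.57) and Vopp1 (−3.27) were lower. Xist, the RNA that silences an X chromosome, had 145 ± 35.4 CPM in NPE, 234 ± 36.2 in KO and 12 ± 3.65 in Rx (−3.60 ± 0.24 against NPE). Tsix reads cannot be excluded from it. These genes had adjusted p of 9.09e-07 or less (edgeR quasi-likelihood, Benjamini-Hochberg). As in KO, stress genes were lower, 12 of 19 falling and 1 rising (13 and 2 adjusted over the list alone, median −1.11; camera adjusted p = 1.18e-08), with Atf5 at −2.02, Atf4 at −0.91 and Trib3 at −2.88. Astrocyte markers fell in 14 of 25 cases and rose in 2 (15 and 4 adjusted over the list alone, median −0.34, camera adjusted p = 7.3e-05), for example Atp1b2 (−1.24) and Aldoc (−0.93). Oligodendrocyte genes fell in 3 of 12 cases (5 adjusted over the list alone, median −0.28, camera adjusted p = 0.00657), namely Bcas1, Olig1 (−0.81) and Olig2 (−0.39).

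A further 5 lists were called between untreated Rx and NPE by camera but not with an estimated correlation. Cell cycle genes were higher in 10 of 32 cases and lower in 1 (12 and 1 adjusted over the list alone, median 0.20; camera adjusted p = 0.00063, adjusted p = 0.0906 with an estimated correlation), such as Mcm7 at 0.74. Neuron genes (2 of 11 lower, 2 adjusted over the list alone, median −0.56, camera adjusted p = 0.00633) included Map2 (−1.38) and Stmn3 (−2.46), both microtubule regulators. Hypoxia genes (6 of 19 lower, 8 lower and 1 higher adjusted over the list alone, median −0.40, camera adjusted p = 0.00543) included Vegfa (−0.92). The neuron and hypoxia lists each had an adjusted p of 0.0906 with an estimated correlation. Interferon genes were lower in 4 of 22 cases (6 adjusted over the list alone, median −0.35; camera adjusted p = 0.0237, adjusted p = 0.158 with an estimated correlation). This call was lost in a fit of the 8 libraries (adjusted p = 0.12) and without NPE replicate 3 (0.136) or Rx replicate 1 (0.0677). Actin and SRF targets were lower in 2 of 15 cases (2 lower and 1 higher adjusted over the list alone, median −0.21; camera adjusted p = 0.0242, adjusted p = 0.0906 with an estimated correlation). Their call was lost without NPE replicate 3 (0.0605) or without the filter (0.0505). Myl9, a myosin light chain, had 0 counts in untreated Rx and was at least 86.9-fold higher in NPE, at 4.36 CPM.

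In NPE, the comparison of BMP-4 with untreated cells asks what the differentiation signal does when ILK is present. Astrocyte genes rose broadly. Of 25, 22 rose and 2 fell (22 and 2 adjusted over the list alone, median log2 fold change 2.78; camera adjusted p = 1.48e-14). The glial filament gene Gfap went from 1.52 ± 0.957 to 216 ± 55 CPM, the protease inhibitor Cst3 from 236 ± 25 to 1755 ± 113 CPM, and the lipid carrier Apoe from 18.1 ± 2.22 to 579 ± 203 CPM. S100b (5.04), Sparcl1 (4.62), Aldoc (2.78) and the sodium pump subunit Atp1b2 (3.34) rose as well. Other large increases were those of Ndrg2 (5.48 ± 0.48), the homeodomain protein gene Hopx (5.24), the adhesion receptor Vcam1 (3.78), Nrep (3.65), the glycogen regulator Ppp1r3c (3.61), the proteoglycan Cspg5 (3.58) and angiotensinogen, Agt (3.47). Calca, which encodes calcitonin gene-related peptide, fell from 419 ± 39 to 4.93 ± 1.48 CPM (−6.38 ± 0.25). The folate enzyme Mthfd2 (−4.78), asparagine synthetase, Asns (−4.22), the arginine transporter Slc7a1 (−4.18) and the aminotransferase Bcat1 (−3.83) fell too. So did the stress gene Nupr1 (−5.55), Tcim (−5.13), Aldh1a3, which makes retinoic acid (−3.69), the matrix gene Tnc (−3.64) and the translation regulator Eif4ebp1 (−3.60). Of 13710 genes, 6132 were called, 3115 higher and 3017 lower with BMP-4 (1759 and 980 with a 2-fold change required). The 20 genes of largest change had a Benjamini-Hochberg-adjusted p of 1.07e-07 or less (edgeR quasi-likelihood).

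Interferon and antigen presentation genes rose in NPE with BMP-4 in 19 of 22 cases (20 adjusted over the list alone, median 2.63; camera adjusted p = 2.09e-12). Ifit1 went from 0.093 ± 0.0837 to 51.8 ± 4.77 CPM, the chemokine Cxcl10 from 6.19 ± 4.99 to 214 ± 18.5, and Stat1 rose by 2.83. Cell cycle genes fell in 27 of 32 cases and rose in 0 (27 and 0 adjusted over the list alone, median −0.90; camera adjusted p = 1.37e-12). Ccnd1, which encodes cyclin D1, fell from 4478 ± 118 to 865 ± 42.8 CPM, and the replication genes Mcm3 (−1.46) and Rrm2 (−1.40) fell less. Of 19 stress genes 16 fell and 1 rose (16 and 1 adjusted over the list alone, median −1.78, camera adjusted p = 1.22e-09), Trib3 by 6.06 and Atf4 by 2.67. Hypoxia genes fell in 14 of 19 cases (15 adjusted over the list alone, median −0.97, camera adjusted p = 2.18e-06), Adm by 2.58 and Vegfa by 2.04. Receptor tyrosine kinase feedback genes fell in 12 of 17 cases and rose in 2 (14 and 2 adjusted over the list alone, median −0.92, camera adjusted p = 7.8e-05), among them Dusp6, a phosphatase of ERK (−2.07), and Phlda1 (−1.69). Direct BMP targets rose in 7 of 20 cases and fell in 3 (7 and 3 adjusted over the list alone, median 0.57, camera adjusted p = 0.0126), with the inhibitors of differentiation Id1 (2.83), Id2 (2.77) and Id3 (1.55). Atoh8 had 3 counts in untreated NPE, and BMP-4 raised it by a ratio of 564 (95% counting interval 192 to 2740).

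Other glial programmes moved in NPE as well. Oligodendrocyte lineage genes rose in 9 of 12 cases and fell in 1 (9 and 1 adjusted over the list alone, median 1.38, camera adjusted p = 0.00116), including Olig1 (1.60), Sox8 (1.91) and the myelin enzyme Cnp (1.88). Ependymal genes rose in 5 of 6 (5 adjusted over the list alone, median 2.86, camera adjusted p = 0.00517). The ciliary regulator Foxj1 went from 10.35 ± 4.15 to 49.3 ± 19.8 CPM, and Cfap126 was at least 49.9-fold higher than its 0 counts untreated. Actin and SRF targets fell in 9 of 15 cases (9 adjusted over the list alone, median −0.43, camera adjusted p = 0.00696), for instance the non-muscle myosin Myh9 (−1.34) and Tagln2 (−0.70). Stem and progenitor genes rose in 12 of 23 cases and fell in 3 (13 and 3 adjusted over the list alone, median 0.58; camera adjusted p = 0.0126, adjusted p = 0.0763 with an estimated correlation). The STAT3 pathway list was not called (9 of 22 rose and 4 fell, median 0.52, camera adjusted p = 0.218). Nor were mesenchymal glioblastoma genes (7 of 26 rose and 10 fell, median −0.11, camera adjusted p = 0.303), where Cebpd rose by 2.36 and Plaur fell by 4.78. Mitochondrially encoded genes took 1.36 ± 0.446% of reads in untreated NPE and 2.44 ± 0.227% with BMP-4 (exact permutation p = 0.0286, n = 4 each), 1.33 ± 0.380% and 1.43 ± 0.449% in KO, and 1.498 ± 0.328% and 1.88 ± 0.468% in Rx (exact permutation p = 0.714 and 0.229).

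The same treatment in KO asks how far this response runs in the line that lacks Ilk. Ncan, a neural proteoglycan that was low in untreated KO, rose by 4.30 ± 0.10 (SE) on the log2 scale. Cdh22 (3.58), Mcc (3.37), Sez6 (3.01) and Id1 (2.97) followed. Calca fell by 5.72 and Tnc by 4.18, with the neurofilament Nefm (−3.59), Tcim (−3.41) and Trp53i11 (−3.39) also lower (edgeR quasi-likelihood, Benjamini-Hochberg-adjusted p of 1.43e-06 or less for these 10). In total 3530 genes were called, 1676 higher and 1854 lower, but 540 higher and 383 lower with a 2-fold change required. BMP targets rose in 12 of 20 cases and fell in 1 (13 and 1 adjusted over the list alone, median 1.0, camera adjusted p = 9.38e-08), with Id2 at 2.25 and Id3 at 1.72. Astrocyte genes rose in 15 of 25 cases and fell in 1 (15 and 1 adjusted over the list alone, median 1.18, camera adjusted p = 1.82e-11), for example Aldoc (2.95), Mlc1 (2.28) and the glutamate transporter Slc1a3 (1.74). Gfap had at most 0.25 CPM in any untreated KO library and 3.77 ± 1.46 CPM with BMP-4, far below its level in BMP-treated NPE. Oligodendrocyte genes (6 of 12 rose, 6 adjusted over the list alone, median 0.52, camera adjusted p = 0.024) and stem genes (7 of 23 rose and 2 fell, 8 and 2 adjusted over the list alone, median 0.24, camera adjusted p = 0.0199) were called, but not with an estimated correlation (adjusted p = 0.0565 and 0.141).

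Several lists that moved in NPE were not called in BMP-treated KO. Cell cycle genes had a median of 0.14 (10 of 32 rose and 6 fell, 11 and 6 adjusted over the list alone, camera adjusted p = 0.411), with Ccnd1 at 6594 ± 586 CPM untreated and 5541 ± 575 with BMP-4. The stress list had a median of −0.11 (3 of 19 rose and 5 fell, 4 and 6 adjusted over the list alone, camera adjusted p = 0.707). Interferon genes had one of 0.54 (6 of 22 rose and 1 fell, camera adjusted p = 0.157) and hypoxia genes one of −0.18 (1 of 19 rose and 6 fell, 2 and 6 adjusted over the list alone, camera adjusted p = 0.181). Cxcl10 had 5.15 ± 3.34 CPM in BMP-treated KO.

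In Rx, BMP-4 again raised astrocyte genes, 19 of 25 rising and 0 falling (20 and 0 adjusted over the list alone, median 2.62, camera adjusted p = 3.48e-16). S100b (4.91), Sparcl1 (4.74), Cspg5 (4.43), Fbxo2, a ubiquitin ligase subunit (3.97), and Ndrg2 (3.91) were the largest increases under the naming rule. Gfap, below its limit on expression, rose by 7.56 to 36.5 ± 5.29 CPM. Calca (−5.08), Tcim (−3.99), Aldh1a3 (−3.63), the vasodilator peptide gene Adm (−3.33) and Trp53i11 (−3.30) fell (edgeR quasi-likelihood, Benjamini-Hochberg-adjusted p of 6.27e-07 or less for these 10). The count was 5047 genes, 2452 higher and 2595 lower, but 1204 higher and 648 lower with a 2-fold change required. Cell cycle genes fell in 21 of 32 cases and rose in 1 (23 and 1 adjusted over the list alone, median −0.52, camera adjusted p = 1.9e-07), Ccnd1 from 5156 ± 129 to 1523 ± 93.4 CPM. Interferon genes rose in 16 of 22 cases (17 adjusted over the list alone, median 1.81, camera adjusted p = 7.54e-07), Ifit1 to 12.3 ± 5.58 CPM. Stress genes fell in 14 of 19 (14 adjusted over the list alone, median −0.76, camera adjusted p = 1.94e-06). Receptor tyrosine kinase feedback genes fell in 10 of 17 (11 lower and 1 higher adjusted over the list alone, median −0.94, camera adjusted p = 0.000401) and hypoxia genes in 10 of 19, with 2 rising (10 and 2 adjusted over the list alone, median −0.72, camera adjusted p = 0.00266).

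BMP targets also rose in Rx, 9 of 20 with 1 falling (10 and 1 adjusted over the list alone, median 0.99, camera adjusted p = 0.000144). So did oligodendrocyte genes, 8 of 12 (8 adjusted over the list alone, median 1.38, camera adjusted p = 0.000144), with Olig1 at 1.67, and ependymal genes, 3 of 6 (5 adjusted over the list alone, median 1.87, camera adjusted p = 0.00693). Actin targets fell in 9 of 15 cases and rose in 1 (10 and 1 adjusted over the list alone, median −0.37, camera adjusted p = 0.00267), among them Tagln2 (−1.58) and Actb (−0.73). Mesenchymal glioblastoma genes fell in 14 of 26 cases and rose in 5 (14 and 5 adjusted over the list alone, median −0.52, camera adjusted p = 0.0146), such as the galectin Lgals1 (−1.29). Stem genes rose in 9 of 23 and fell in 3 (11 and 3 adjusted over the list alone, median 0.41, camera adjusted p = 0.0174). The last 2 calls did not hold with an estimated correlation (adjusted p = 0.0581 and 0.0913).

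Whether the lines differ in their BMP-4 response was tested by the difference of responses itself. Each genotype is a single line here, so an effect of ILK cannot be told apart from other differences between the lines. These include the shifts of chromosomes given below. Between KO and NPE the difference of responses was called for 3602 genes, 1855 with a more positive and 1747 with a more negative change in KO. The balance turned to 726 and 954 with a 2-fold difference required and to 1716 and 1876 with RLE size factors. Mthfd2, a mitochondrial folate enzyme, fell far less in KO. It went from 134 ± 5.8 to 80.5 ± 8.72 CPM in KO and from 642 ± 105 to 23.4 ± 3.87 in NPE, a difference of responses of 4.04 ± 0.19 (SE). The difference was 3.89 for Asns, 3.61 for Slc7a1, 3.58 for Nupr1, 3.35 for Bcat1, 3.31 for Eif4ebp1, 2.96 for the gluconeogenic enzyme Pck2 and 2.90 for Shmt2, and also 3.29 for Ndrg1 and 3.20 for Adamtsl4. The change was more negative in KO for Hopx (−4.76 ± 0.46), Apoe (−3.83), Sparcl1 (−3.20, but 5.03 over NPE untreated), Ndrg2 (−3.09) and Hey1, a Notch target (−2.95). So it was for Rcan2 (−3.46), the nuclear RNA Neat1 (−3.29), the adhesion gene Cadm4 (−2.96), Vcam1 (−2.93) and the kinase Dapk1 (−2.77). All 20 had a Benjamini-Hochberg-adjusted p of 0.000891 or less (edgeR quasi-likelihood, interaction term). Shmt2 lies on chromosome 10, Neat1 on chromosome 19, and Apoe, Cadm4 and Nupr1 on chromosome 7.

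By lists, the 3 smallest p for a difference between the responses of KO and NPE were those of cell cycle genes (24 of 32 more positive and 0 more negative, 27 and 0 adjusted over the list alone, median 0.99, camera adjusted p = 3.33e-17), interferon genes (18 of 22 more negative, 19 adjusted over the list alone, median −2.90, camera adjusted p = 3.03e-12) and stress genes (15 of 19 more positive, 15 adjusted over the list alone, median 1.64, camera adjusted p = 5.33e-12). Astrocyte genes responded less in 10 of 25 cases and more in 3 (12 and 4 adjusted over the list alone, median −1.54, camera adjusted p = 3.48e-05). Cst3 rose by 2.89 in NPE and 0.66 in KO, whereas Aldoc rose by 2.78 and 2.95. The fall of hypoxia genes was smaller in KO, more positive in 9 of 19 (9 adjusted over the list alone, median 0.59, camera adjusted p = 0.000299). Receptor tyrosine kinase feedback genes (8 of 17 more positive and 1 more negative, 8 and 2 adjusted over the list alone, median 0.92, camera adjusted p = 0.00184) and oligodendrocyte genes (5 of 12 more negative and 1 more positive, 7 and 1 adjusted over the list alone, median −1.0, camera adjusted p = 0.0413) were not called with an estimated correlation (adjusted p = 0.0598 each). The latter call also ended without BMP-treated NPE replicate 4 (0.0522).

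Over the 3115 genes that BMP-4 raised in NPE, the median log2 fold change was 1.16 in NPE, 0.32 in KO and 0.77 in Rx, and over the 3017 lowered genes −0.77, −0.23 and −0.55. Since these genes were chosen by their response in NPE, values in the other lines lie nearer to 0 by that choice alone. Of the raised genes 889 (28.5%) and of the lowered genes 1064 (35.3%) were called in the same direction in KO, against 1807 (58%) and 1965 (65.1%) in Rx. The response was smaller than in NPE or opposite to it by the interaction test in 2776 genes in KO and 614 in Rx. In KO, 170 of the raised and 191 of the lowered genes were called in the opposite direction, against 29 and 34 in Rx.

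**Figure D4:**
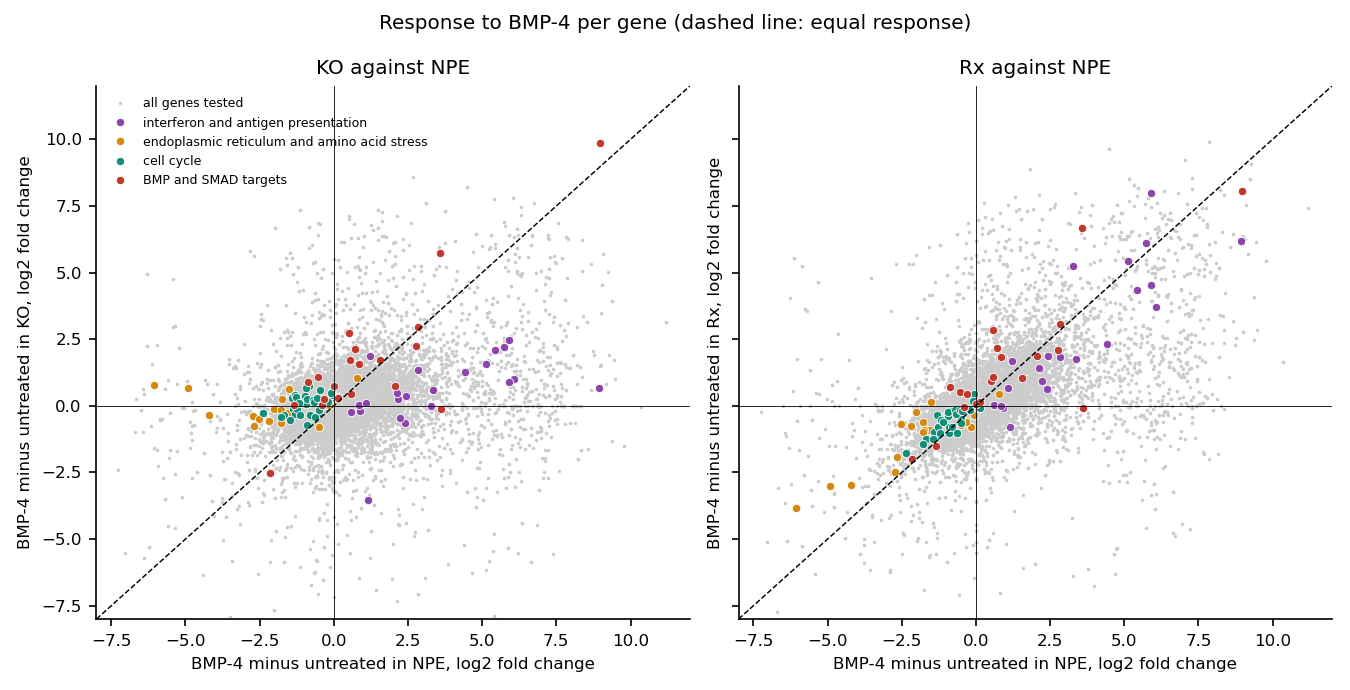
Log2 fold change with BMP-4 in NPE (horizontal) against that in KO (left) or Rx (right), 1 point per tested gene, with members of 4 gene lists coloured and a dashed line where both responses are equal. Over genes raised in NPE the median was 1.16 in NPE, 0.32 in KO and 0.77 in Rx.

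Rx and KO differed in their responses at 1663 genes, 791 more positive and 872 more negative in Rx (367 and 212 with a 2-fold difference required). Sparcl1 (3.33), Hopx (2.83), the neurotrophic factor receptors Gfra2 (3.33) and Gfra1 (2.58) and Fam102a (2.45) responded more positively in Rx. Asns (−2.65), Bcat1 (−2.57), Mthfd2 (−2.53), Slc7a1 (−2.36) and the immediate early gene Egr1 (−2.21) responded more negatively. Each of the 10 had an adjusted p of 0.00141 or less (edgeR quasi-likelihood, Benjamini-Hochberg). Cell cycle genes had a median difference of −0.62 (18 of 32 more negative, 23 adjusted over the list alone, camera adjusted p = 1.13e-15) and stress genes one of −0.71 (9 of 19, 11 adjusted over the list alone, camera adjusted p = 6.68e-09). Interferon genes had one of 1.34 (7 of 22 more positive, 11 adjusted over the list alone, camera adjusted p = 6.37e-07) and astrocyte genes one of 0.87 (8 of 25 more positive and 1 more negative, 11 and 1 adjusted over the list alone, camera adjusted p = 4.63e-06). Receptor tyrosine kinase feedback (9 of 17 more negative and 1 more positive, 11 and 1 adjusted over the list alone, median −0.58, camera adjusted p = 0.000264), actin (5 of 15 more negative and 1 more positive, 9 and 1 adjusted over the list alone, median −0.45, camera adjusted p = 0.0106) and oligodendrocyte genes (5 of 12 more positive and 1 more negative, 7 and 1 adjusted over the list alone, median 0.82, camera adjusted p = 0.0106) followed. The hypoxia list (5 of 19 more negative, 8 more negative and 1 more positive adjusted over the list alone, median −0.58, camera adjusted p = 0.0226) lost its call with an estimated correlation (adjusted p = 0.163), without untreated Rx replicate 3 (0.0588) and without BMP-treated KO replicate 2 (0.0667).

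Between Rx and NPE 852 genes differed in response, 460 of them more positive in Rx (158 more positive and 147 more negative with a 2-fold difference required). Insm1, a neuroendocrine transcription factor (2.49), Nupr1 (2.38), Ndrg1 (2.26), the caveolar protein gene Cavin2 (2.25) and G0s2, an inhibitor of lipolysis (2.12), were more positive. Apoe (−3.52), Hey1 (−2.60), Vcam1 (−2.48), the actin-associated Synpo (−2.20) and Il17rd (−2.16) were more negative (edgeR quasi-likelihood, Benjamini-Hochberg-adjusted p of 0.00054 or less). Apoe reached 16.8 ± 2.59 CPM in BMP-treated Rx against 579 ± 203 in NPE. Interferon genes had a median of −0.92 (6 of 22 more negative, 10 adjusted over the list alone, camera adjusted p = 5.68e-09) and stress genes one of 0.79 (10 of 19 more positive, 12 more positive and 2 more negative adjusted over the list alone, camera adjusted p = 2.6e-07). Cell cycle genes had one of 0.40 (8 of 32 more positive, 12 more positive and 1 more negative adjusted over the list alone, camera adjusted p = 2.6e-07) and cell cycle inhibitors one of 0.35 (4 of 14 more positive and 2 more negative, 7 and 2 adjusted over the list alone, camera adjusted p = 0.0145). Hypoxia genes (5 of 19 more positive and 1 more negative, 6 and 1 adjusted over the list alone, median 0.33, camera adjusted p = 0.00191) were not called with an estimated correlation (adjusted p = 0.0607).

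Compared directly, BMP-treated KO and NPE differed at 5071 genes, 2531 higher and 2540 lower in KO (834 and 1144 with a 2-fold difference required). All 32 cell cycle genes were higher in KO (32 adjusted over the list alone, median 1.18, camera adjusted p = 9.04e-24), Ccnd1 by 2.68, Rrm2 by 1.75 and Plk1 by 1.57. Interferon genes were lower in 20 of 22 cases (21 adjusted over the list alone, median −2.43, camera adjusted p = 9.7e-14), among them the class I genes H2-K1 (−1.04) and B2m (−0.70). Isg15 had 2 counts in KO against 43.9 CPM in NPE, a ratio of 1390 (95% counting interval 385 to 11400), and Bst2 had 0 counts and was at least 89.2-fold lower. Astrocyte genes were lower in 18 of 25 cases and higher in 5 (18 and 5 adjusted over the list alone, median −1.99, camera adjusted p = 5.4e-09), among them Cst3 (−3.15), Atp1b2 (−2.77) and glutamine synthetase, Glul (−2.17). Stem genes (14 of 23 lower and 2 higher, 14 and 2 adjusted over the list alone, median −0.66, camera adjusted p = 0.000597) and oligodendrocyte genes (7 of 12 lower and 2 higher, 7 and 2 adjusted over the list alone, median −0.86, camera adjusted p = 0.00286) were lower too. Cavin2 (5.07), Adh7 (4.50), Trf (4.33), Il33 (3.55) and the semaphorin receptor Nrp2 (3.19) were the largest increases under the naming rule. Nnat (−9.96), Rbp1 (−8.28), Apoe (−5.22), Vcam1 (−4.57) and the mitochondrial carrier Ucp2 (−4.46) were the largest decreases (edgeR quasi-likelihood, Benjamini-Hochberg-adjusted p of 1.17e-07 or less).

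The remaining lists called between BMP-treated KO and NPE were not called with an estimated correlation. They were receptor tyrosine kinase feedback (9 of 17 higher and 1 lower, 9 and 1 adjusted over the list alone, median 0.49, camera adjusted p = 0.0029), stress (12 of 19 higher and 1 lower, 12 and 1 adjusted over the list alone, median 0.67, camera adjusted p = 0.00501), heat shock and RNA handling (7 of 12 higher and 2 lower, 7 and 2 adjusted over the list alone, median 0.47, camera adjusted p = 0.0354), each with an adjusted p of 0.0634 with an estimated correlation. The last was extracellular matrix (5 of 23 higher and 10 lower, 6 and 10 adjusted over the list alone, median −0.79; camera adjusted p = 0.0354, adjusted p = 0.228 with an estimated correlation). Dusp6 was higher by 1.65, the chaperone gene Hsp90aa1 by 0.90, and the collagen gene Col4a1 lower by −2.43. In a fit of the 8 libraries the heat shock and matrix calls ended (adjusted p = 0.0942 and 0.225), as they did without NPE replicate 3 for the former (0.0507) and KO replicate 3 for the latter (0.0576).

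With BMP-4, Rx and KO differed at 3725 genes, 1887 higher and 1838 lower in Rx (758 and 471 with a 2-fold difference required). Rbp1 (8.39), Nnat (6.02), Tnc (4.6), Trip6 (4.59) and Ucp2 (3.94) were higher. Trf (−6.71), Bcas1 (−5.40), Adh7 (−5.28), Xist (−3.72) and Cavin2 (−3.70) were lower (edgeR quasi-likelihood, Benjamini-Hochberg-adjusted p of 1.13e-09 or less). Cell cycle genes were lower in 25 of 32 cases (27 adjusted over the list alone, median −0.67, camera adjusted p = 8.19e-14), and astrocyte genes higher in 15 of 25 and lower in 2 (15 and 3 adjusted over the list alone, median 1.49, camera adjusted p = 1.3e-05). Stress genes were lower in 13 of 19 and higher in 1 (14 and 2 adjusted over the list alone, median −0.63, camera adjusted p = 0.000154) and interferon genes higher in 11 of 22 (12 adjusted over the list alone, median 0.87, camera adjusted p = 0.000333). Matrix genes (11 of 23 higher and 4 lower, 12 and 4 adjusted over the list alone, median 0.97, camera adjusted p = 0.00062), stem genes (9 of 23 higher and 2 lower, 9 and 3 adjusted over the list alone, median 0.55, camera adjusted p = 0.00145) and actin targets (9 of 15 lower and 1 higher, 9 and 1 adjusted over the list alone, median −0.42, camera adjusted p = 0.013) were called as well. Receptor tyrosine kinase feedback (8 of 17 lower and 1 higher, 8 and 1 adjusted over the list alone, median −0.31, camera adjusted p = 0.013), fibroblast and mural genes (4 of 7 higher, 4 adjusted over the list alone, median 0.86, camera adjusted p = 0.0296) and BMP receptors and signal genes (6 of 14 higher, 6 adjusted over the list alone, median 0.32, camera adjusted p = 0.0381), among them the co-receptor gene Neo1 (2.02), were not called with an estimated correlation (adjusted p = 0.108, 0.0753 and 0.108). The last was also not called in a fit of the 8 libraries (0.0696).

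Between BMP-treated Rx and NPE, 2261 genes differed, 1151 higher and 1110 lower in Rx. The balance turned to 239 and 374 with a 2-fold difference required and to 1096 and 1196 with RLE size factors. The basement membrane gene Fras1 (2.82), Lrrn3 (2.78), Ndrg1 (2.73), Nupr1 (2.13) and the netrin receptor Unc5b (2.13) were higher. Apoe (−5.11), Xist (−4.20), Nnat (−3.95), Bcas1 (−3.91) and Sez6 (−3.51) were lower (edgeR quasi-likelihood, Benjamini-Hochberg-adjusted p of 2.22e-07 or less). Cell cycle genes were higher in 27 of 32 cases (29 adjusted over the list alone, median 0.54, camera adjusted p = 3.03e-18). Cell cycle inhibitors were higher in 7 of 14 and lower in 2 (8 and 2 adjusted over the list alone, median 0.33, camera adjusted p = 0.0109, and 0.105 in a fit of the 8 libraries). Interferon genes were lower in 18 of 22 (19 adjusted over the list alone, median −1.65, camera adjusted p = 3.32e-15), such as H2-K1 (−1.16). Astrocyte genes were lower in 12 of 25 and higher in 3 (15 and 3 adjusted over the list alone, median −0.84, camera adjusted p = 6.7e-09), Cst3 by −1.12 and the gap junction gene Gja1 higher by 1.29. Oligodendrocyte genes (5 of 12 lower, 5 adjusted over the list alone, median −0.52, camera adjusted p = 0.00124), actin targets (6 of 15 lower and 2 higher, 7 and 2 adjusted over the list alone, median −0.35, camera adjusted p = 0.00968) and mesenchymal glioblastoma genes (10 of 26 lower and 3 higher, 12 and 5 adjusted over the list alone, median −0.37, camera adjusted p = 0.00968) were lower. Unc5b lies on chromosome 10, whose genes as a whole were higher in Rx, and Apoe and Nupr1 lie on chromosome 7.

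Fitted fold changes of genes with 3 or fewer counts in a group depend on the prior count. With such genes at their bound or ratio, and left out where both groups were that low, the median of the astrocyte list became −0.92 for KO against NPE untreated, 0.93 for Rx against KO with BMP-4 and 2.11 for BMP-4 in Rx. For the differences of responses it became −0.81 between KO and NPE and 0.34 between Rx and KO, and that of the interferon list −2.40 and 1.16. Over the 43 called lists with such genes, a median moved by at most 0.735.

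Markers of cell types that the cultures were not meant to hold were low. Over all libraries the median member of the microglia and leukocyte list had 0.00599 CPM (3 of 15 genes tested), that of the endothelial list 0.195 CPM (5 of 11) and that of the fibroblast and mural list 0.283 CPM (7 of 14), with Hexb at 26.9, Flt1 at 15.4 and Col5a1 at 86.8 CPM as their highest genes. For KO against NPE untreated none of these was called (camera adjusted p = 0.916, 0.355 and 0.643). The fibroblast and mural list was called higher in Rx than in KO with BMP-4, as given above, but not with an estimated correlation.

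Genes were then grouped by chromosome, since cultured lines can gain or lose copies. Genes of chromosome 19 were lower in KO than in NPE, with a median log2 fold change of −0.45 untreated and −0.48 with BMP-4 over 465 genes. Of these, 198 were called lower and 19 higher untreated, and 196 and 33 with BMP-4 (camera over chromosomes, adjusted p = 1.93e-12 and 1.52e-08). Genes of chromosome 10 were higher in Rx than in NPE, by medians of 0.47 and 0.49 over 629 genes, 260 called higher and 12 lower untreated and 255 and 13 with BMP-4 (adjusted p = 2.23e-22 and 7.71e-21). Chromosome 7, which carries Ilk, was higher in untreated KO by a median of 0.34 over 1079 genes (323 higher and 96 lower, adjusted p = 0.000175), and by 0.12 with BMP-4, which was not called (adjusted p = 0.375). Per library, chromosome 19 lay at −0.425 ± 0.0264 in untreated KO and at 0.0055 ± 0.0246 in untreated NPE, and chromosome 10 at 0.493 ± 0.017 in untreated Rx and 0.0015 ± 0.0222 in NPE (mean log2 shift ± SD, n = 4). Chromosome 7 lay at 0.336 ± 0.0368 in untreated KO against 0.00175 ± 0.0271 in NPE, and at 0.136 ± 0.0392 in BMP-treated KO against 0.012 ± 0.054 in NPE. Each of these shifts had an exact permutation p of 0.0286, the smallest possible. Without the genes of these 3 chromosomes, an alternative added after the data had been seen, 3236 genes were called for KO against NPE untreated, 1351 for Rx against NPE untreated and 2990 for the difference of responses between KO and NPE.

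**Figure D5:**
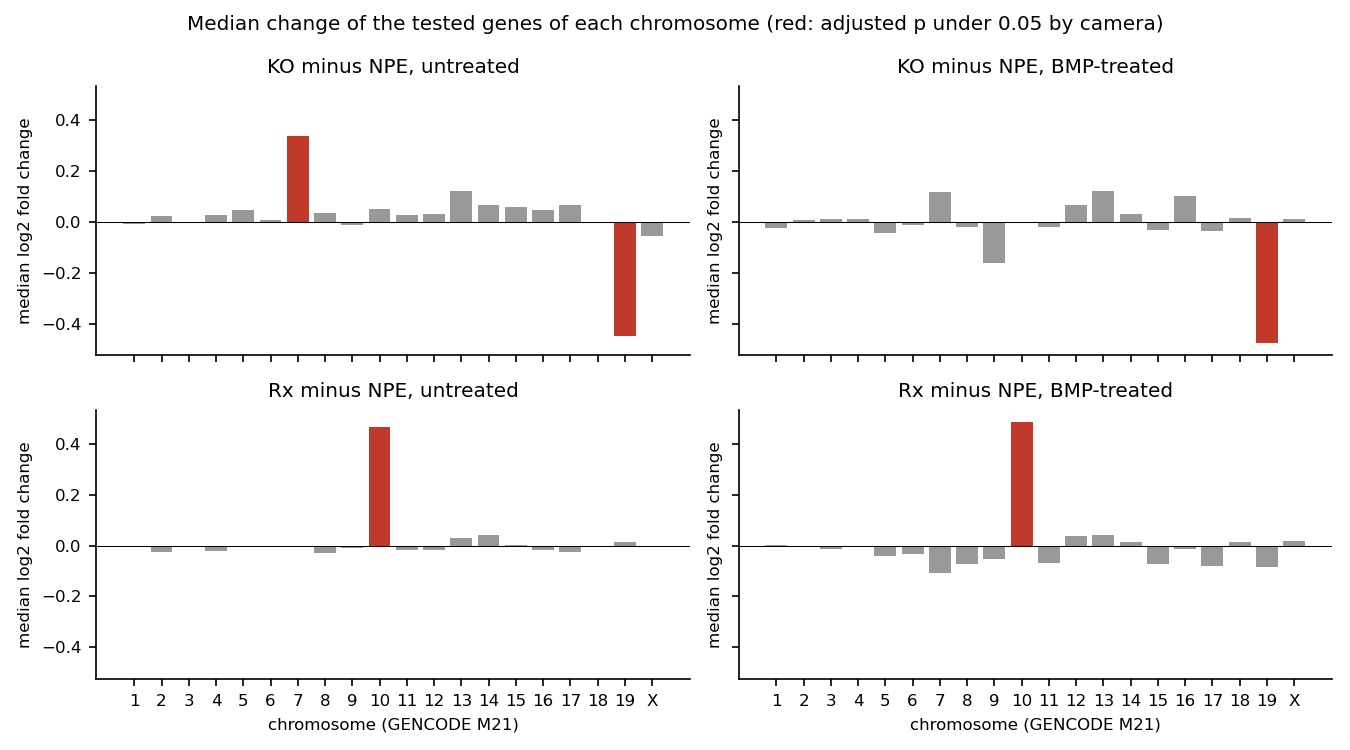
Median log2 fold change of the tested genes of each chromosome in 4 comparisons of lines, red where camera over chromosomes gave an adjusted p under 0.05. Chromosome 19 lay at −0.45 in untreated KO against NPE and chromosome 10 at 0.47 in untreated Rx against NPE.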

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

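The predictions on weaker BMP-4 exposure, unedited cells and the Ilk level of Rx were written after the result that their test measures had been seen, and all others before it. Of 90 groups of 4 libraries looked at, 4 held a library far from its group, where chance alone would give about 5%. They were gene reads in BMP-treated Rx replicate 1 (15706400, the others 12837200 to 13081500), Ilk in BMP-treated KO replicate 4 (13.96 CPM, the others 17.47 to 17.66), Pten in BMP-treated KO replicate 2 (11.64 CPM, the others 15.86 to 16.27) and Stat3 in untreated NPE replicate 1 (306 CPM, the others 247.1 to 256.1). In data that the comparisons do not use, reads outside genes came to 6.39% of gene reads in untreated KO, 5.80% in untreated Rx, 6.27% in BMP-treated NPE, 6.03% in BMP-treated KO and 5.90% in BMP-treated Rx, above the 5.12% of untreated NPE (exact permutation p = 0.0286 each, n = 4 each).

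All other values of this part stand here because a test of the difference itself found the lines' BMP-4 responses to differ. The counts were 3602 genes between KO and NPE, 1663 between Rx and KO and 852 between Rx and NPE. Between KO and NPE the list medians were −1.54 for astrocyte (−0.81 with genes of few counts at their bounds), −1.0 for oligodendrocyte lineage, 0.987 for cell cycle, 0.924 for receptor tyrosine kinase feedback, −2.90 for interferon, 0.589 for hypoxia and 1.64 for stress genes, of which the oligodendrocyte and receptor tyrosine kinase lists were not called with an estimated correlation (adjusted p = 0.0598 each). Between Rx and KO they were −0.45 for actin, 0.868 for astrocyte (0.34 with such bounds), 0.822 for oligodendrocyte lineage, −0.622 for cell cycle, −0.576 for receptor tyrosine kinase feedback, 1.34 for interferon, −0.584 for hypoxia (adjusted p = 0.163 with an estimated correlation, so not called) and −0.715 for stress genes. Between Rx and NPE they were 0.404 for cell cycle, 0.349 for cell cycle inhibitors, −0.922 for interferon, 0.329 for hypoxia (adjusted p = 0.0607 with an estimated correlation, so not called) and 0.788 for stress genes.

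Single genes between KO and NPE were Mthfd2 4.04, Asns 3.89, Slc7a1 3.61, Nupr1 3.58, Bcat1 3.35, Eif4ebp1 3.31, Ndrg1 3.29, Adamtsl4 3.20, Pck2 2.96, Shmt2 2.90, Hopx −4.76, Apoe −3.83, Rcan2 −3.46, Neat1 −3.29, Sparcl1 −3.20, Ndrg2 −3.09, Cadm4 −2.96, Hey1 −2.95, Vcam1 −2.93, Dapk1 −2.77, Ilk −0.80, Egfr −0.66 and Stat3 −0.66. Between Rx and KO they were Sparcl1 3.33, Gfra2 3.33, Hopx 2.83, Gfra1 2.58, Fam102a 2.45, Asns −2.65, Bcat1 −2.57, Mthfd2 −2.53, Slc7a1 −2.36 and Egr1 −2.21. Between Rx and NPE they were Insm1 2.49, Nupr1 2.38, Ndrg1 2.26, Cavin2 2.25, G0s2 2.12, Apoe −3.52, Hey1 −2.60, Vcam1 −2.48, Synpo −2.20, Il17rd −2.16, Ilk −0.66 and Pten 0.88. The last 2 calls (edgeR quasi-likelihood, Benjamini-Hochberg-adjusted p = 0.0192 for Ilk and 0.0438 for Pten) were lost in fits without single libraries, with an adjusted p of 0.0591 to 0.0794 in 8 fits for Ilk and up to 0.115 in 11 fits for Pten.

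For the smaller BMP-4 response of KO, weighed first, RLE size factors gave 3592 genes, of which 3463 were among the 3602. RLE and the trimmed mean of M values both assume that most genes keep their level. This count therefore cannot exclude an error that they share. Such an error moves all genes of a library the same way. The response in KO was smaller or opposite at 1302 genes raised and at 1474 genes lowered in NPE. Since both directions are concerned, this argues against library scaling as the only cause. The BMP and SMAD targets argue against a weaker exposure of the KO cultures that would lower the response of these targets. Their median difference of responses was 0.639 over all 20 members, with 3 called smaller and 3 larger in KO. The interval, 0.136 to 1.28, is a bootstrap over genes and holds no error between cultures. Over the 7 members raised in NPE the median was 0.134, against −0.848 over all genes raised in NPE. How these targets depend on the dose was not measured, so a weaker exposure that leaves their response unchanged was not excluded. That untreated KO already lay at the level that BMP-4 brings could not be told. Of the 2776 genes with a smaller or opposite response, 43.2% differed in untreated KO in that direction and 7.85% in the opposite one. Both comparisons share the untreated NPE libraries, which raises the former share and lowers the latter. By the medians given above, the stress list was lower in untreated KO by nearly as much as BMP-4 lowered it in NPE. Loss of ILK, the biological explanation the design gives, was not excluded, and it cannot be told apart from other differences between the lines. The median response of Rx, 0.77 at genes raised and −0.55 at genes lowered in NPE, lay between those of KO and NPE, but choosing genes by their response in NPE alone pulls Rx towards 0. Some list medians of Rx lay outside the range of KO and NPE. Examples are the mesenchymal glioblastoma list (median −0.11 in NPE, −0.43 in KO and −0.52 in Rx) and the matrix list (−0.213, −0.067 and 0.107). No difference of responses was called for either list between any of the lines, so they do not set Rx outside that range. For the matrix list the median difference of responses was −0.27 between Rx and KO, though its medians rose from KO to Rx.

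Ilk reads left in the KO libraries were weighed second. Unedited cells among the KO cells are argued against by 23 genes whose highest KO library kept less of the NPE level than 0.5 of the share that Ilk kept, such as Rbp1 with at most 0.483% untreated and 0.445% with BMP-4. Reads of Taf10 were not excluded. With BMP-4 in KO, Ilk changed by −0.719 and Taf10 by −0.537 (difference −0.182, SE 0.163). Ilk was 3.89% to 5.62% of Taf10 in KO. In Rx Ilk changed by −0.578, so a fall does not tell Taf10 reads from Ilk's. A partly deleted transcript with an intact 3' end was not tested: the deletion is not given.

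Differences between Rx and NPE were weighed last. A chromosome 10 gain in Rx fits for genes there (median 0.47 untreated, 0.49 with BMP-4). Of 1868 genes called 272 lie there, and 1303 stayed called without chromosomes 7, 10 and 19. Effects on genes elsewhere were not tested. A second active X chromosome is argued against by the median of X-linked genes, −0.00707 untreated and 0.0171 with BMP-4. A low level of Ilk tags in Rx is argued against by the difference of Ilk from NPE, 0.38 untreated and −0.282 with BMP-4. Tags outside the deleted part, or from Taf10, do not show how much working ILK the cells have. No protein was measured here, so too little ILK protein in Rx was not excluded. A lasting effect of having lacked ILK was not tested.

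Splits of the same libraries into other groups of the same size showed how many genes other groupings of them call. For the 9 comparisons of groups, each with 35 splits, the real grouping called 3128 and 5284 genes (KO against NPE untreated and with BMP-4), 3147 and 4612 (Rx against KO), 1402 and 2984 (Rx against NPE), 5208 (BMP-4 in NPE), 3596 (in KO) and 5551 (in Rx) in fits of the 8 libraries, and the highest other split 0. For the differences of responses, 100 random splits included the real one, which called 3186 (KO and NPE), 1982 (Rx and KO) and 839 (Rx and NPE), against at most 1864, 838 and 755 elsewhere. In each case only 1 split, the real one, called as many. In the comparisons of groups, every other split mixes libraries of both groups, which raises the spread, so few calls were likely in advance. No split can show whether differences between cultures or lines arose by chance. The highest other splits of the responses exchanged 2 libraries per line in the untreated groups and 0 in the BMP-treated ones, so they still hold differences between the lines.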

How the results depend on the processing

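All 12 counts of called genes stayed within 1.5 times of the reported ones with RLE size factors, no filter, DESeq2, only the groups compared, the replicate block and thinning to 10050219 reads, a depth limit set by the smallest library. With a 2-fold change also required they fell to 1538, 614 and 1231 untreated (KO and NPE, Rx and NPE, Rx and KO), 1978, 613 and 1229 with BMP-4, 2739 (NPE), 923 (KO) and 1852 (Rx) for BMP-4, and 1680, 305 and 579 for the differences of responses, as that rule leaves fewer genes by construction. The replicate block, for which the pairing check gave no ground (60 pairs, r of −0.086 to 0.042), gave 3915 against 4106 genes for KO and NPE untreated. Which direction held more genes was not stable in most comparisons: with BMP-4 in Rx, 2452 higher and 2595 lower became 2666 and 2337 with RLE, 2600 and 2289 without the filter and 2801 and 2418 with DESeq2. RLE moved the median change of all genes with BMP-4 in NPE from 0.0543 to 0.107.

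Of 276 list tests, fry called 170 against 89, and 1 reversed, extracellular matrix with BMP-4 in NPE (adjusted p = 0.0188); fry asks another question than camera, and an estimated correlation left 61. Lists with fewer than 3 genes gave no value 16 times in fits of only the groups compared and 12 times after thinning. The median response of Rx at genes lowered in NPE, −0.55, was −0.537 with RLE, −0.539 without the filter and −0.537 with DESeq2, and that at raised genes, 0.77, was 0.814 without the filter. Without single libraries these ranged from −0.561 to −0.526 and from 0.775 to 0.820. Of 1254 results for named genes 121, and of 276 list results 111, changed their call in some setting. The block weakened 15 and strengthened 1 of the former, RLE 7 and 2, DESeq2 7 and 17, no filter 14 and 12, thinning 6 and 5. For all these the cause was not tested.

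Without single libraries the counts were 3698 to 4049, 2955 to 3150 and 1491 to 1945 untreated (KO and NPE, Rx and KO, Rx and NPE), 4569 to 4777, 3202 to 3356 and 1803 to 2218 with BMP-4, 5618 to 5821, 3023 to 3208 and 4472 to 4709 for BMP-4 in NPE, KO and Rx, and 3219 to 3636, 1361 to 1570 and 669 to 1036 for the differences of responses. Called lists ranged from 87 to 93 and reversed genes from 1998 to 2219.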

Other observations

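Some responses to BMP-4 in KO went beyond or against those in NPE, the only line they were set against here. At 1019 genes the change in KO was called and larger than, or opposite to, that in NPE, 495 raised and 524 lowered, and at 361 of them the changes were called in opposite directions. These 361 genes are also among the 2776 with a smaller or opposite response. The genes named next were chosen after their values had been seen. The imprinted gene Mest rose in KO from 789 ± 178 to 2283 ± 163 CPM and fell in NPE from 2789 ± 325 to 1257 ± 319, with log2 fold changes of 1.53 and −1.15. Ndrg1, a stress and hypoxia gene, rose by 2.01 and fell by 1.28. Ndrg1, Insm1 and G0s2, all among these genes, also responded more positively in Rx than in NPE, by 2.26, 2.49 and 2.12. For them the difference from NPE was thus not particular to KO. Nkx2-2, a transcription factor of oligodendrocyte precursors, rose by 1.06 and fell by 0.96, and Cyp26b1, which degrades retinoic acid, rose by 1.44. The membrane receptor Gper1 rose in KO by 2.41 and the metalloprotease Adam12 by 2.15, whereas NPE had changes of −0.02 and 0.04 that were not called. Untreated, Gper1 differed between KO and NPE by −4.18 on the log2 scale. These genes are called by edgeR's quasi-likelihood test with a Benjamini-Hochberg-adjusted p under 0.05 (SD of CPM, n = 4 each).

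Reads without a unique alignment, which the tests do not use, fell with BMP-4 in every line, from 107 ± 6.44% of gene reads to 89.9 ± 4.18% in NPE, from 111 ± 3.96% to 82.1 ± 0.854% in KO and from 110 ± 7.61% to 83.9 ± 3.40% in Rx (SD, n = 4 each; exact permutation p = 0.0286 each).

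For the lower level of chromosome 19 genes in KO, loss of a copy in a part or all of the cells was put forward as a hypothesis, written down after the chromosome's median but before the values of its parts had been seen. It predicts a shift along the whole chromosome. In 3 equal parts of its tested genes, in gene order, the median log2 fold change between KO and NPE was −0.42, −0.54 and −0.39 untreated and −0.62, −0.44 and −0.38 with BMP-4. The highest untreated value was −0.393, which fits the hypothesis, although no DNA was measured. Rx, at 0.031 ± 0.0234 per library untreated (mean log2 shift ± SD, n = 4), did not share the shift. On chromosome 7 the parts differed, at 0.19, 0.20 and 0.59 untreated and −0.16, −0.02 and 0.56 with BMP-4.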
